A study of Mus musculus with 9 samples.

How the data were processed

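Bulk RNA sequencing was done on hepatic stellate cells, the vitamin A storing pericytes of the liver, from mice with chemically injured livers. Per the labels' protocols, mice received 6 injections of carbon tetrachloride (CCl4, a hepatotoxin) at intervals of 3 days, and stellate cells were isolated 2 days after the last one by density centrifugation and flow sorting on the autofluorescence of their stored retinoids, then lysed at once. The labels put 5 libraries in a control group (floxed Yap1 without Cre) and 4 in a YAP-deleted group (floxed Yap1 with Cre driven by the Lrat promoter, which is active in stellate cells). Group and library code were taken from the sample titles, and the columns of the deposited file were matched to them by library code. The column used for LYT013 was headed LYT013.1, whereas every other header equalled its library code. The reason for this suffix is not given in the sources used here. The labels do not say in words that each library came from a separate mouse, so the p-values measure the spread between these libraries, part of which may be technical.

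The extraction protocol in the labels describes a poly-A preparation and a ribosomal depletion preparation, both with Illumina TruSeq chemistry, and which of them each library received is not given in the sources used here. Per the submitters' processing notes, bcl2fastq 2.20, kallisto 0.44.0 and sleuth were used and the builds GRCm38, mm10 and GRCh38 were named, with no order or role. The file deposited by the authors held variance-stabilised values on a log2-like scale, 1 value per gene name and library. It had 35024 rows, of which 13872 held the lowest value of 4.96 in every library. The step that made these values is not given in the sources used here. Of the gene names, 34802 (99.4%) matched the reference gene names, 26 had been turned into dates, and 2 were listed more than once.

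From the values themselves, each library followed the inverse hyperbolic sine form of a count divided by a size factor, and inverting it gave whole numbers to within 0.1 for 100.0% of the values above the lowest one in every library. The recovered totals ran from 14052502 counts (control LYT017) to 31816055 (the library labelled YAP-deleted LYT013). Normalised counts in the text are these recovered counts divided by the size factor of their library. Because the deposited unit was a transformed value and no count table, the planned count models were not run. Differences are therefore given on the log2-like scale, which understates the change of genes with few counts.

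Genes above the lowest value in at least 4 libraries were tested, which left 17203. The test was limma 3.58.1 in R 4.3.3, with a linear model on group, empirical Bayes moderation with a mean-variance trend, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Yap1 also had an exact two-sided permutation test over every regrouping of the 9 libraries. Of 32 gene lists, 31 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists. The erythroid list had 4 tested members and was not tested. Camera with an estimated correlation and fry were run beside it. The lists, the tests, the alternatives and the rule for the named genes were set before the data were examined. The rule named Yap1, 16 fixed genes, up to 10 genes per direction with the largest change among those past the threshold (with no overlap between the groups and at least the median level, or the 5 genes with the smallest p where none passed), and up to 4 members with the smallest p of each list described.

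Leaving out the libraries LYT013 and LYT014, whose Yap1 level went against their labels, was chosen after seeing the data, as were limma voom on the recovered counts, fits within each range of library codes, and the removal of a smooth trend in transcript length and GC content from each library. The alternatives set beforehand were repeated on the remaining 7 libraries. They covered filters, scaling between libraries, the transformation, the moderation, library weights, covariates and the omission of each library in turn. No group was reassigned from its values. Gene positions, transcript lengths and GC content came from GENCODE release M21 on GRCm38.

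The procedure was tested on simulated counts with the means and depth of these libraries and known changes in 200 genes, with no structure shared between genes. The changed genes were drawn from those at or above the median level. In both runs the spread within groups came from the 7 libraries without LYT013 and LYT014. The shares given for 9 libraries therefore leave out the spread that LYT013 and LYT014 add, and may be too high for that comparison. With 9 libraries and 17201 genes, limma recovered 51.5%, 89.6% and 97.0% of the changes of 0.5, 1 and 2 log2 units, and 5.9% of its calls were false. With 7 libraries and 17176 genes the shares were 22.7%, 83.6% and 97.0%, and 4.2% of the calls were false.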

Results

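The study asked how deletion of Yap1, the transcriptional coactivator that the Hippo pathway restrains, changes hepatic stellate cells in livers injured by repeated CCl4. The 9 libraries comprised 5 labelled control (LYT004, LYT005, LYT014, LYT015 and LYT017) and 4 labelled YAP-deleted (LYT006, LYT008, LYT013 and LYT016). Total counts recovered from the deposited values ran from 14052502 (control LYT017) to 31816055 (the library labelled YAP-deleted LYT013), and 16282 to 17341 genes per library lay above the lowest value. Collagen and decorin transcripts led every library, with Col3a1 or Dcn as the most abundant gene at 1.44% to 2.11% of the counts.

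Yap1 (chromosome 9, 7931999 to 8004596 on GRCm38, minus strand) was about 5 times lower in 3 of the 4 libraries labelled YAP-deleted than in 4 of the 5 libraries labelled control. LYT004, LYT005, LYT015 and LYT017 had 2910, 2924, 3663 and 3561 normalised Yap1 counts, and LYT006, LYT008 and LYT016 had 644, 650 and 647. The other 2 libraries went against their labels. The library labelled control LYT014 had 620 counts, and the library labelled YAP-deleted LYT013 had 2537. As labelled, the Yap1 difference was −1.30 ± 0.54 log2 units (SE, 4 against 5 libraries), with a limma adjusted p = 0.649 and an exact two-sided permutation p = 0.0794 over 126 regroupings. The difference was −2.07 among library codes 4 to 8, where every library followed its label, and −0.63 among codes 13 to 17, which hold both of the contradicting libraries. The deposited values are given per gene name and not per exon, and the labels do not say which exon is floxed. The remaining counts may therefore include reads from exons outside the deleted part. Every direction below that includes the libraries labelled LYT013 and LYT014 rests on labels that their Yap1 level contradicts.

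**Figure D1:**
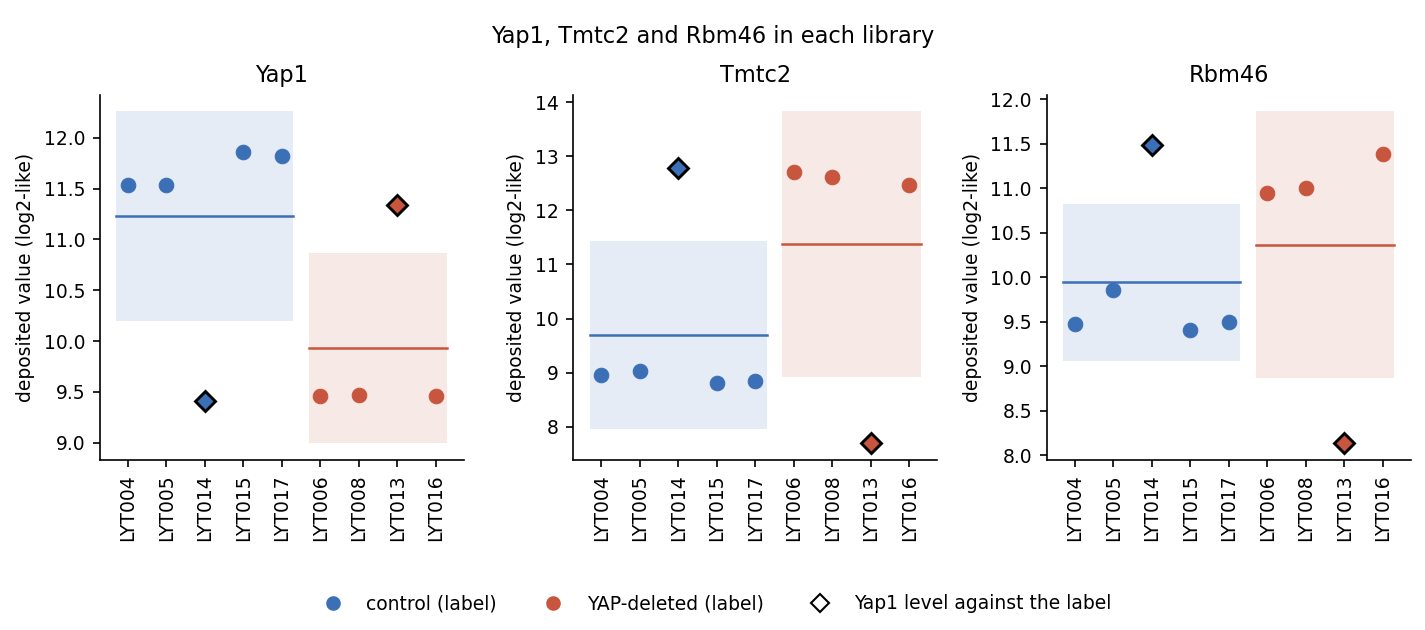
Deposited log2-like value (y axis) of Yap1, Tmtc2 and Rbm46 in each library (x axis), coloured by label; lines and shading give the mean and SD of each labelled group, and diamonds mark the libraries labelled LYT013 and LYT014. Yap1 read 9.41 in the library labelled control LYT014 and 11.34 in the library labelled YAP-deleted LYT013, and both libraries also lay on the other group's side for Tmtc2 and Rbm46.

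With all 9 libraries as labelled, no gene differed between the groups after adjustment. Fibrillar collagen transcripts, the main product of activated stellate cells, varied widely within each group. Col1a1 averaged 87080 ± 71125 normalised counts in the control libraries (SD, n = 5) and 44781 ± 31595 in the YAP-deleted libraries (SD, n = 4), a difference of −0.76 ± 0.64 log2 units (SE). Acta2, the smooth muscle actin of myofibroblasts, differed by −0.98 ± 0.64, and Lox, a collagen crosslinking enzyme, by −1.30 ± 0.57. The YAP target genes Ccn1, Ccn2 and Ankrd1 differed by −0.62 ± 0.27, 0.19 ± 0.24 and −0.43 ± 0.26. Col1a2, Col3a1, Timp1, Pdgfrb, Hgf, Lrat and the YAP paralog Wwtr1 differed by −0.53, −0.45, −0.16, −0.16, −0.66, −0.26 and −0.25, and Cxcl12, Des and Tgfb1 by 0.13, 0.22 and 0.28, all with limma adjusted p-values between 0.649 and 0.890.

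Limma called 0 of 17203 genes higher and 0 lower in the libraries labelled YAP-deleted, and limma voom on the recovered counts also called 0. At an unadjusted p under 0.05 there were 1242 genes by limma and 1319 by voom, against 860 expected by chance. The groups did not overlap for 2.84% of the genes, against 1.59% expected by chance. The 5 genes with the smallest p among those higher were Endog and Tmem158, with differences of 0.59 ± 0.12 and 0.52 ± 0.11 log2 units (SE), and F9, Syndig1l and Gm17994. The last 3 were listed at 0 in every control library and averaged 4.00, 2.24 and 1.77 normalised counts in the libraries labelled YAP-deleted. The filter asked for at least 4 libraries above the lowest value. A gene at 0 in all 5 control libraries could pass it only if present in all 4 libraries labelled YAP-deleted. The separation of these 3 genes was thus fixed by the filter, which the 1.59% does not allow for. Among those lower the 5 genes with the smallest p were the matrix glycoprotein Tnc (−0.90 ± 0.16), the neuronal nitric oxide synthase Nos1 (−1.06 ± 0.23), the kinase anchoring protein Akap6 (−0.84 ± 0.18), Gm3055 (−0.64 ± 0.14) and Arhgap29 (−0.55 ± 0.11). None of the 10 passed, all at a limma adjusted p of 0.649. Without LYT013 and LYT014 the counts were 3 higher and 9 lower, and they are described further on.

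In the 9 libraries as labelled, camera with the preset correlation called 7 gene lists lower and 2 higher in the libraries labelled YAP-deleted, and none of the 9 with an estimated correlation. All 34 tested cell cycle genes had a negative difference (median −0.81, camera adjusted p = 0.000196), as did 15 of 16 basement membrane genes (median −0.29, adjusted p = 0.00559) and 20 of 30 fibrillar matrix genes (median −0.21, adjusted p = 0.00998). With an estimated correlation these had adjusted p = 0.980, 0.958 and 0.980. Hippo pathway components (median −0.22, adjusted p = 3.38e-05), PDGF and integrin genes (median −0.17, adjusted p = 0.00998), contractile genes (median −0.22, adjusted p = 0.0435) and YAP and TAZ target genes (median −0.13, adjusted p = 0.0413) were also lower by camera. Their adjusted p-values with an estimated correlation were 0.958, 0.648, 0.958 and 0.648. The cytosolic ribosomal proteins (median 0.30, adjusted p = 1.59e-07) and oxidative phosphorylation genes (median 0.25, adjusted p = 1.6e-06) were higher, both with adjusted p = 0.958 with an estimated correlation. The library labelled YAP-deleted LYT013 stood apart in both: its ribosomal mean was 13.31 against 12.22 to 12.52 in the others, and without it the medians were 0.09 and 0.07, with camera adjusted p-values of 0.0163 and 0.0367.

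No member of these lists passed over all genes. Adjusted over the list alone, Tnc was lower in the fibrillar matrix list and Pdgfd, a PDGF receptor ligand, in the PDGF and integrin list, and no member of the other lists passed. The other 22 lists had camera adjusted p-values from 0.0681 to 0.947. Without LYT013 the YAP and TAZ target, fibrillar matrix, basement membrane, and PDGF and integrin lists were not called, with medians of −0.08, −0.09, −0.05 and −0.10 and camera adjusted p-values of 0.0906, 0.411, 0.167 and 0.0690. The contractile call ended without LYT004, LYT005, LYT006, LYT016 or LYT017 (adjusted p up to 0.621), and the cell cycle call without LYT005 or LYT016 (up to 0.119). The fibrillar call also ended without LYT004, LYT005 or LYT016, and the YAP and TAZ target call without LYT006, LYT015, LYT016 or LYT017.

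**Figure D2:**
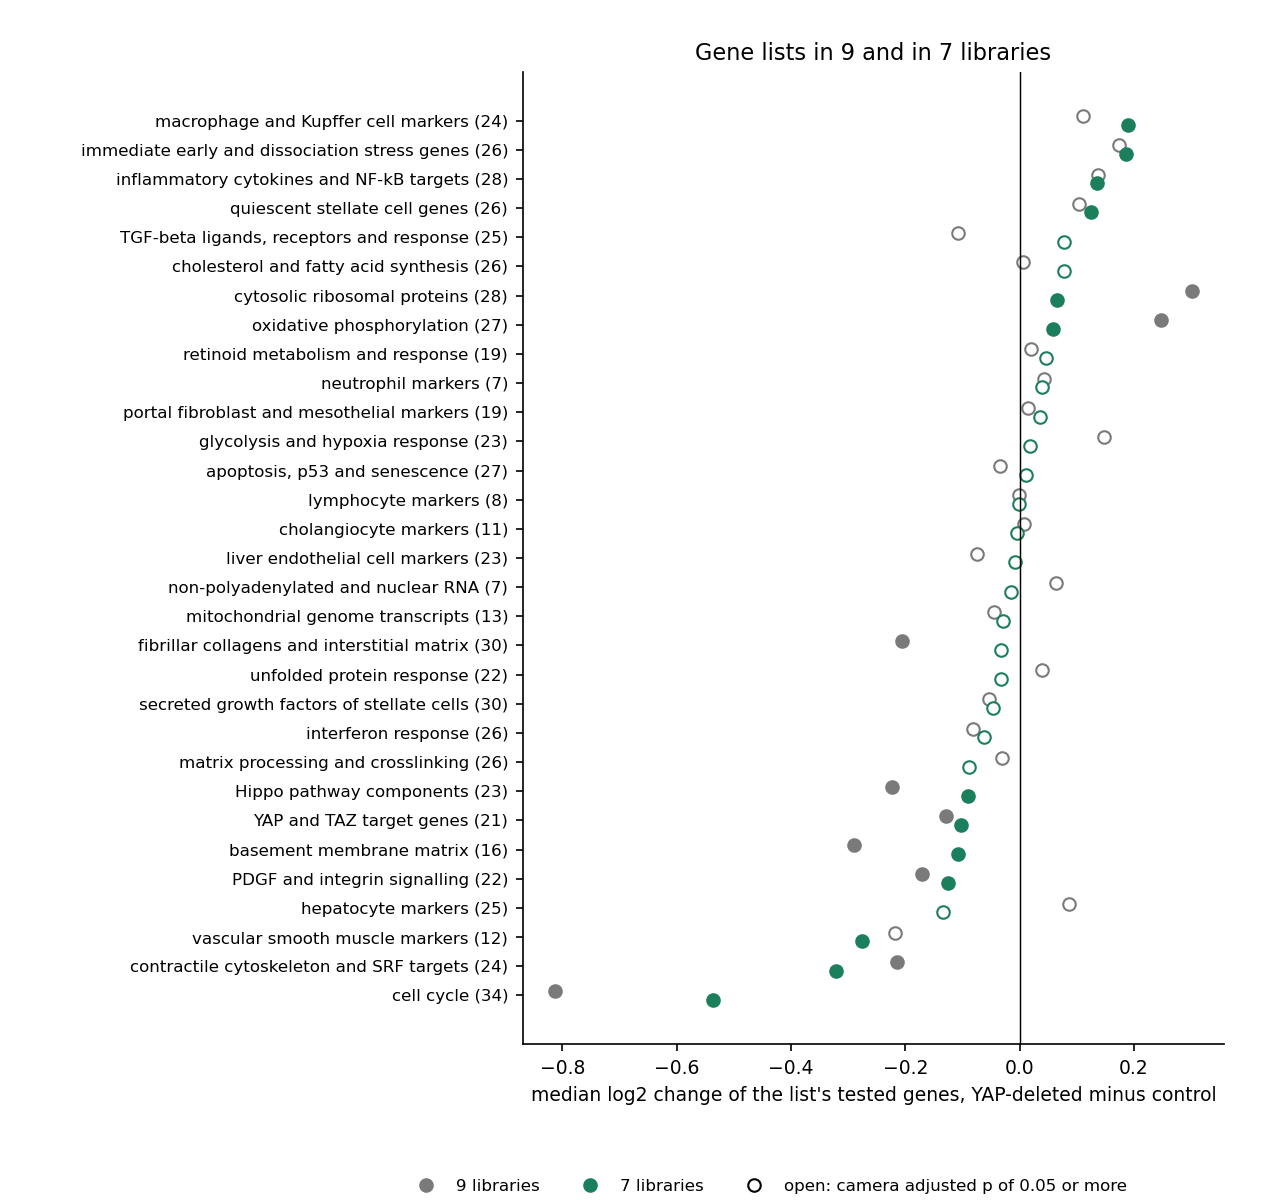
Median log2 difference (x axis, YAP-deleted minus control) of the tested genes of each list (y axis, number tested in parentheses), in all 9 libraries as labelled and in the 7 left without LYT013 and LYT014; filled points had a camera adjusted p under 0.05 with the preset correlation. Cell cycle genes had the lowest medians (−0.81 and −0.54), and the ribosomal median was 0.30 with 9 libraries and 0.07 with 7.

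In the 7 libraries whose Yap1 level followed their labels (4 control, 3 YAP-deleted), 12 genes differed, 3 higher and 9 lower in the YAP-deleted libraries. By label, all YAP-deleted libraries carry the Cre and no control does. An effect of the Cre transgene therefore cannot be told apart from an effect of Yap1 loss, for these genes or for the gene lists. The same holds for the 9 libraries as labelled. Tmtc2, which encodes a membrane protein of the endoplasmic reticulum, rose 14.6-fold, from 424 ± 34.9 to 6200 ± 507 normalised counts (SD, n = 4 and 3), a difference of 3.69 ± 0.09 log2 units (SE, limma adjusted p = 8.32e-07). Rbm46, which encodes an RNA-binding protein, rose from 701 ± 114 to 2178 ± 383 (1.55 ± 0.14, limma adjusted p = 0.00798), and Ackr4, an atypical chemokine receptor, rose 2.60-fold (1.15 ± 0.13, limma adjusted p = 0.0323). Tnc, a matrix glycoprotein of injured tissue, fell from 7323 ± 546 to 3410 ± 396 normalised counts (SD, n = 4 and 3), a difference of −1.09 ± 0.11 log2 units (SE, limma adjusted p = 0.0110). Ogn, a small leucine-rich proteoglycan, fell from 625 ± 145 to 120 ± 24.8, a difference of −1.94 ± 0.17 (limma adjusted p = 0.00647).

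The desmosomal plakophilin Pkp2 fell by 1.51 ± 0.13 log2 units (SE), Nos1 by 1.41 ± 0.12, the receptor phosphatase Ptprf by 1.38 ± 0.18, the kinase anchoring proteins Akap12 by 1.19 ± 0.14 and Akap6 by 0.73 ± 0.09, and the focal adhesion protein Lims2 by 1.18 ± 0.14, with limma adjusted p-values from 0.00647 to 0.0499. The log2-like scale understates falls at low counts: Nos1 went from 181 to 38.5 normalised counts, a 4.69-fold fall. Pkp2, Lims2 and Akap12 lie outside the naming rule for this fit and were named after their values were seen. Yap1 fell by 2.22 ± 0.10 (adjusted p = 8.08e-05), which is not independent, since its level decided which libraries were left out. Rbm46 lies on chromosome 3 at 82837228 to 82876483, 16.1 kb from Lrat, whose promoter drives the Cre, and Tmtc2 on chromosome 10 at 105187663 to 105574451. Lrat (82892579 to 82903973) differed by −0.14 ± 0.22 (limma adjusted p = 0.957), and it overlaps Rbm46os, annotated on the opposite strand at 82876705 to 82943638, with 0 shared exon bases. Of the tested protein-coding genes within 1 Mb, Rbm46 was the 1 of 15 near Lrat past the threshold, and 0 of 3 near Tmtc2 and 0 of 17 near Yap1 were.

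The fixed stellate cell genes did not pass in the 7 libraries. Ccn1 averaged 27703 ± 5142 normalised counts in the control libraries and 14558 ± 3964 in the YAP-deleted libraries (SD, n = 4 and 3), a difference of −0.95 ± 0.23 log2 units (SE, limma adjusted p = 0.520). Ccn2 and Wwtr1 differed by 0.04 ± 0.28 and −0.09 ± 0.09, and Ankrd1, with 21.1 normalised counts in controls, by −0.70 ± 0.25. Acta2, Lox, Col1a1, Col1a2 and Col3a1 differed by −1.49 ± 0.71, −1.17 ± 0.71, −0.63 ± 0.79, −0.52 ± 0.50 and −0.38 ± 0.54. Des, Pdgfrb, Hgf, Timp1, Cxcl12 and Tgfb1 differed by between −0.23 and 0.24. The adjusted p-values of these genes ran from 0.520 for Ccn1 to 0.985 for Ccn2.

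The number of genes called in the 7 libraries moved with single libraries and with covariates. It was 1 higher and 5 lower without LYT004, 1 higher and 1 lower without LYT006, and 5, 4 and 4 lower without LYT008, LYT016 and LYT017. It was 7 higher and 18 lower with the library code set as covariate, and 8 higher and 17 lower with the macrophage mean as covariate. At an unadjusted p under 0.05 limma gave 1082 genes, and the groups did not overlap for 7.32% of the genes, against 5.71% expected by chance. With limma voom on the recovered counts, 2 genes were higher and 5 lower (Tmtc2, Rbm46, Yap1, Pkp2, Ogn, Nos1 and Tnc), all among the 12. Tmtc2 passed under each of the 22 alternatives tried, Pkp2, Ogn and Nos1 under 21, Rbm46 under 20, Tnc under 18, Ackr4 and Akap12 under 15, and Akap6 and Ptprf under 10 and 9. Lims2 passed under 14 of 21. Tnc was lost without LYT004, LYT006, LYT016 or LYT017.

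In these 7 libraries camera with the preset correlation called the contractile list lower in the YAP-deleted libraries. Of 24 tested contractile cytoskeleton and SRF target genes, 21 had a negative difference (median −0.32, camera adjusted p = 5.96e-06, and adjusted p = 0.520 with an estimated correlation). None passed over all genes, and 2 passed adjusted over the list alone: the myosin light chain Myl9 (−1.47 ± 0.31 log2 units, SE) and the actin-binding Tagln (−1.15 ± 0.28). With all 9 libraries as labelled these 2 genes differed by −0.47 ± 0.61 and −0.47 ± 0.48. The library labelled YAP-deleted LYT013, left out here, had the highest contractile mean of the 9 libraries, at 12.51. Of 12 vascular smooth muscle genes, 9 had a negative difference (median −0.28, camera adjusted p = 0.0143, and adjusted p = 0.520 with an estimated correlation), and the receptor Notch3 (−1.31 ± 0.24) and the integrin Itga7 (−0.93 ± 0.20) passed adjusted over the list alone and none over all genes. This call ended without LYT006 (adjusted p = 0.0553). With all 9 libraries as labelled the vascular smooth muscle list was not called (camera adjusted p = 0.389), and its highest mean was that of LYT013 (9.85). Basement membrane genes had a median of −0.11 (camera adjusted p = 0.0152, and adjusted p = 0.520 with an estimated correlation), with Lama2 at −0.79 ± 0.22 and Lama4 at −0.82 ± 0.35, and no member passed over all genes or adjusted over the list alone. That call ended without LYT004, LYT005, LYT006 or LYT016 (adjusted p from 0.0658 to 0.0843). Fibrillar matrix genes had 15 negative and 15 positive differences (median −0.03, camera adjusted p = 0.163), and Tnc was the 1 that passed, over all genes and adjusted over the list alone.

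YAP and TAZ target genes were lower by camera in these 7 libraries by a small margin (13 of 21 negative, median −0.10, adjusted p = 0.0486, and adjusted p = 0.520 with an estimated correlation). Ccn1, the phosphatase Ptpn14 (−0.37 ± 0.08 log2 units, SE) and Tgfb2 (−0.52 ± 0.13) passed adjusted over the list alone, and none over all genes, while Crim1 differed by 0.43 ± 0.14. The call ended without LYT004, LYT006, LYT015, LYT016 or LYT017 (adjusted p from 0.0661 to 0.194), and with the library code set as covariate (median −0.11, adjusted p = 0.124), and was lost under 14 of 24 alternatives. Of 23 Hippo pathway components, which include Yap1 itself, 16 were negative (median −0.09, camera adjusted p = 0.000799, and adjusted p = 0.684 with an estimated correlation). Yap1, whose level decided which libraries were left out, passed over all genes, and Yap1 and Ptpn14 passed adjusted over the list alone. Without Yap1 the list had a median of −0.09 with 15 of 22 negative (camera adjusted p = 0.0143, and adjusted p = 0.812 with an estimated correlation). PDGF and integrin genes had a median of −0.12 (camera adjusted p = 0.0343, and adjusted p = 0.520 with an estimated correlation), with Pdgfd (−0.41 ± 0.09) passing adjusted over the list alone and none over all genes. It was not called without LYT004, LYT006 or LYT016 (adjusted p from 0.0553 to 0.153).

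Cell cycle genes were lower in the YAP-deleted libraries of the 7 by camera (34 of 34 negative, median −0.54, adjusted p = 0.0152, and adjusted p = 0.812 with an estimated correlation), but no member passed over all genes or adjusted over the list alone. The list mean was 9.74 and 10.15 in control LYT004 and LYT005, 7.18 and 7.03 in control LYT015 and LYT017, 9.69 in YAP-deleted LYT008, and 7.22 and 6.99 in YAP-deleted LYT006 and LYT016. Mki67, a marker of cycling cells, differed by −1.10 ± 1.53 log2 units (SE, limma adjusted p = 0.950). Both groups held libraries at the high and at the low level, and the call ended without LYT004, LYT005, LYT006 or LYT016 (adjusted p from 0.342 to 0.844). The cell cycle call also ended with the macrophage mean as covariate (median −0.03, camera adjusted p = 0.773). With library weights (arrayWeights) it ended as well (median −0.21, camera adjusted p = 0.356).

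**Figure D3:**
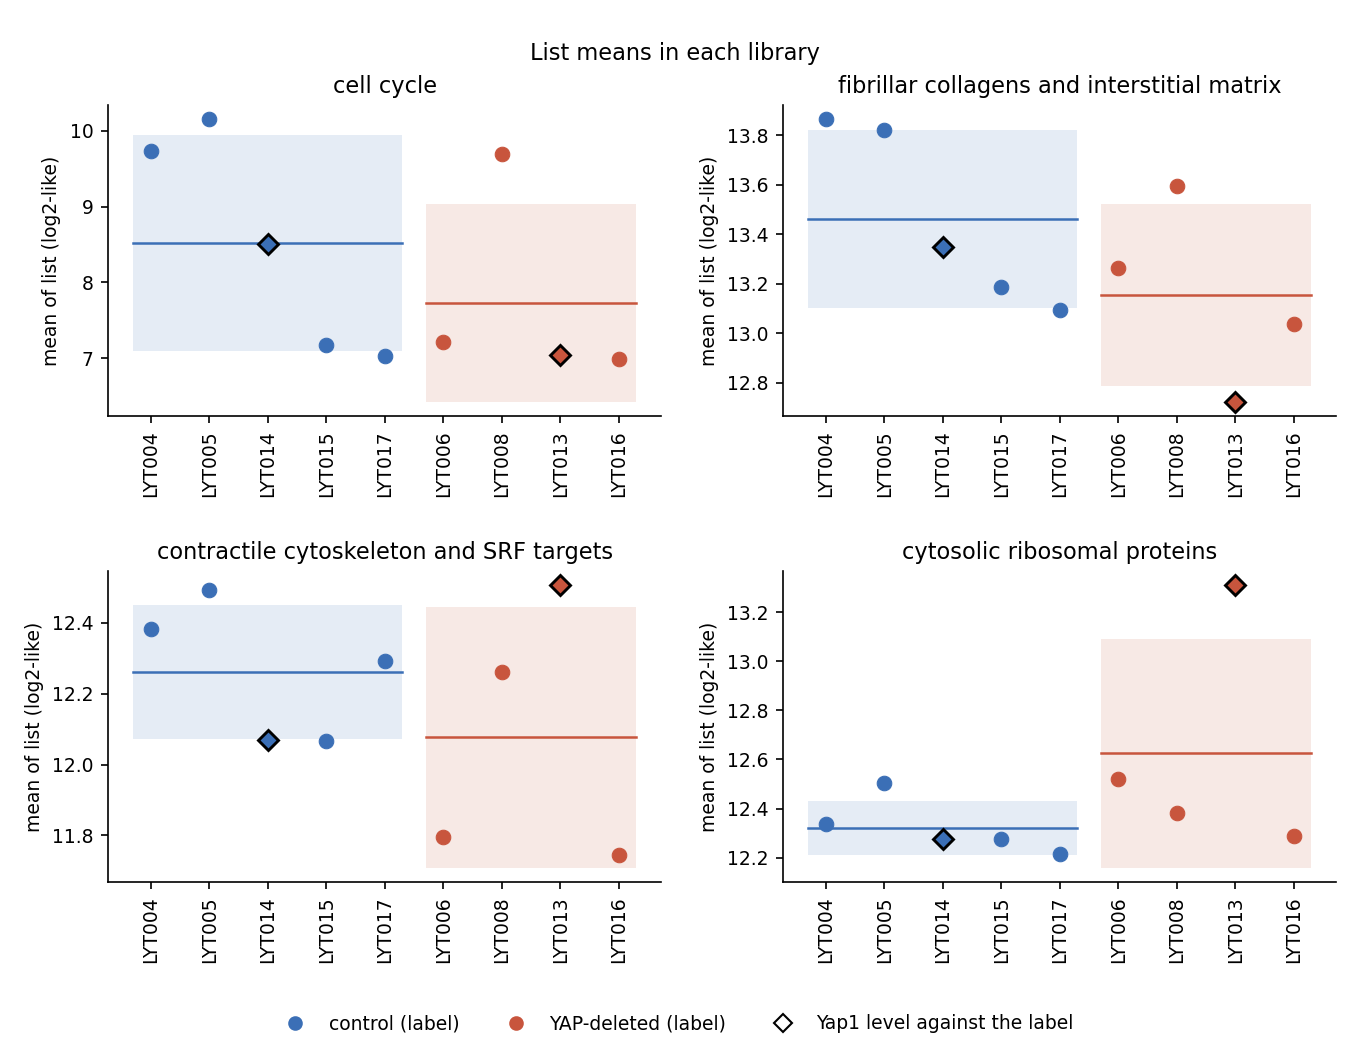
Mean log2-like value (y axis) of 4 gene lists in each library (x axis), coloured by label, with the mean and SD of each labelled group as line and shading; diamonds mark the libraries labelled LYT013 and LYT014. Cell cycle means were 9.69 to 10.15 in LYT004, LYT005 and LYT008 and at most 8.51 in the others, and the ribosomal mean of the library labelled YAP-deleted LYT013 was 13.31.

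In the YAP-deleted libraries of the 7, immediate early and dissociation stress genes (median 0.19, adjusted p = 0.0143) and inflammatory cytokines (median 0.14, adjusted p = 0.0343) were higher by camera. So were quiescent stellate cell genes (median 0.13, adjusted p = 0.0413), macrophage and Kupffer cell markers (median 0.19, adjusted p = 0.0343), ribosomal proteins (median 0.07, adjusted p = 0.0413) and oxidative phosphorylation (median 0.06, adjusted p = 0.0486). With an estimated correlation each of these 6 had an adjusted p = 0.812. No member of the 6 lists passed over all genes or adjusted over the list alone. Of 26 quiescent stellate cell genes, 18 had a positive and 8 a negative difference. The quiescence transcription factor Lhx2 differed by 0.37 ± 0.11 log2 units (SE) and Hand2 by 0.36 ± 0.13, whereas Lrat and Hgf differed by −0.14 ± 0.22 and −0.23 ± 0.20. The early response gene Ier2 differed by 0.49 ± 0.15. Klf6 of the immediate early and dissociation stress list differed by −0.37 ± 0.14 and Cxcl14 of the inflammatory list by −0.63 ± 0.16. Macrophage markers averaged 6.63 ± 0.38 in the control libraries and 6.80 ± 0.47 in the YAP-deleted libraries (SD, n = 4 and 3), and the median of the list was −0.10 without LYT016 (camera adjusted p = 0.597). Each of the 6 calls ended when certain single libraries were left out. The immediate early and dissociation stress call ended without LYT005 or LYT017 (adjusted p up to 0.166), and the inflammatory call without LYT004, LYT005, LYT016 or LYT017 (up to 0.228). The quiescence call ended without LYT004, LYT005, LYT006 or LYT016 (up to 0.534), and the macrophage call without LYT004, LYT005 or LYT016 (up to 0.768). The ribosomal call ended without LYT004, LYT006, LYT008, LYT015 or LYT017 (up to 0.868), and the oxidative phosphorylation call without any of these or LYT016 (up to 0.558). With the macrophage mean as covariate the immediate early and dissociation stress, inflammatory and quiescence calls ended (camera adjusted p = 0.0530, 0.0943 and 0.487). Their medians were then 0.20, 0.10 and 0.03, so the first was not smaller than without the covariate. With the length and GC trend removed the immediate early and dissociation stress call ended (median 0.15, camera adjusted p = 0.0758). The quiescence, macrophage, ribosomal and oxidative phosphorylation calls ended too (camera adjusted p from 0.0782 to 0.126), with medians of 0.10, 0.16, 0.06 and 0.05. With the library code set as covariate the ribosomal and oxidative phosphorylation calls also ended (camera adjusted p = 0.239 and 0.0660), with medians of 0.04 and 0.07.

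Markers of other cells that the sort could hold were not called by camera in the 7 libraries, apart from the macrophage and vascular smooth muscle lists. Hepatocyte markers had a median of −0.13 (adjusted p = 0.362), liver endothelial markers −0.01 (adjusted p = 0.650), cholangiocyte markers −0.01 (adjusted p = 0.595), portal fibroblast and mesothelial markers 0.04 (adjusted p = 0.617), lymphocyte markers 0.00 (adjusted p = 0.762) and neutrophil markers 0.04 (adjusted p = 0.595). The endothelial mean was highest in the library labelled control LYT014, at 8.42 against 6.73 to 7.86 in the others. Mitochondrial genome transcripts had a median of −0.03 (adjusted p = 0.595), and non-polyadenylated and nuclear RNA −0.02 (adjusted p = 0.806). The mean and median differed in sign for the endothelial, cholangiocyte, mitochondrial, and non-polyadenylated lists.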

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

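The tests on Tmtc2, on mixtures of cells, in the 7 libraries and within codes 4 to 8 were chosen after the result was seen. Of 136 groups of libraries examined, 17 had a library whose gap to the nearest other one, as a share of the group's range, passed Dixon's 95% value, where chance flags about 1 in 20 groups (6.8 here). LYT013 gave 9 of the 17, LYT014 6 and LYT008 2, and the genes among them include those called without LYT013 and LYT014, which were picked for a small spread in the rest.

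In the control group the library labelled LYT014 was lowest for Yap1 (gap share 0.867), Nos1 (0.717) and Pkp2 (0.780) and highest for Ackr4 (0.878), Rbm46 (0.783) and Tmtc2 (0.942). In the YAP-deleted group the library labelled LYT013 was highest for Yap1 (0.994), Des (0.893), Akap12 (0.894), Lims2 (0.893), Pkp2 (0.937) and oxidative phosphorylation (0.932), and lowest for Rbm46 (0.864), Tmtc2 (0.953) and cholesterol and fatty acid synthesis (0.841). LYT008 was the highest YAP-deleted library for the cell cycle (0.917) and for apoptosis, p53 and senescence genes (0.856).

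For the Yap1 levels of LYT013 and LYT014, the tables argue against both libraries being mixtures of both groups, since Yap1 in LYT014 lay at 1.01 of the way from the control mean (0) to the YAP-deleted mean (1). A mixture in LYT013 alone stays open. On a linear scale its Tmtc2 lay at −0.047, below the control mean by more than the control SD of 0.006. That met the bound against a mixture, which was set after the result was seen and rests on 1 gene. On the same linear scale Yap1 lay at 0.28, Ackr4 at 0.16, Ogn at 0.323, Nos1 at 0.613, Ptprf at 0.745 and Tnc at 0.843. Akap12, Rbm46, Pkp2 and Lims2 lay below the control mean, as Tmtc2 did, at −0.021, −0.324, −0.797 and −1.797. Akap6 lay beyond the YAP-deleted mean, at 1.637. The 11 genes called in the other libraries besides Yap1 ran from −1.80 to 1.64. A Cre-carrying LYT013 that kept Yap1 also stays open. Its Rbm46 lay at −0.92 on the log2-like scale. This bears on the Cre only if Rbm46 follows the transgene and not the loss of Yap1, which coincide in the other 7 libraries. The bound for it was written before this test, but after Rbm46 was seen to rise in Cre-carrying libraries. It did not allow for this coincidence. Exchanged labels or columns stay open too: 72.7% of the 11 genes in LYT013 and 90.9% in LYT014 lay nearer to the other group's mean on that scale, where at least 80% in both had been set beforehand. On Tmtc2, chosen later, LYT014 lay at 1.05 and LYT013 at −0.33 on that scale, in line with an exchange or a wrong label in each, and no label was changed.

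LYT013 stood apart over all genes, with 1138 genes more than 1 log2 unit from the other libraries against 137 to 353, and a median correlation with them, across genes that are not independent, of 0.970. Its higher depth is argued against as the whole cause: thinned to the lowest total it stayed at 0.954, with the next library at 0.962. The same holds for reads shared between similar genes, since it stayed at 0.968 against 0.977 without predicted, pseudogene and ribosomal names. A bias in transcript length and GC content may contribute and stays open: the trend took up 0.272 of the variance of its deviations against at most 0.0623 elsewhere, and after its removal LYT013 stood at 0.978 against 0.979, a gap of 0.0015 within the SD of 0.0029 of the others. No biological explanation was tested.

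Cell cycle genes were high in LYT004, LYT005 and LYT008, which share the codes 4 to 8, a candidate batch. LYT006, the remaining library of those codes, had a mean of 7.22, within the 6.99 to 8.51 of codes 13 to 17, which argues against the code set as the whole cause. A difference in cell division between libraries stays open and was not tested.

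With 9 libraries the real split gave 0 genes, so that all 100 splits drawn had to give at least as many and their count decides nothing, and the highest other split gave 444. With 7 libraries 3 of 35 splits, the real one included, gave at least the real 12, which does not exclude chance. The highest other split, LYT004, LYT005 and LYT008 against the rest, gave 1205. The split along the code sets (LYT015, LYT016 and LYT017) gave 579. Both point to a structure of the samples, and the count of splits cannot tell chance from it. Each remaining split gave at most 1 gene. With the code set as a covariate the real split gave 7 higher and 18 lower genes, and within codes 4 to 8 alone 1 higher and 2 lower.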

How the results depend on the processing

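Alternatives in the 7 libraries, within code sets, with voom, with the Hippo list without Yap1 and with the length and GC trend removed were chosen after seeing the data. With 9 libraries no gene was called under any alternative except without LYT013 and LYT014 (3 higher, 9 lower, Yap1 −2.22, now past the threshold, as the choice of libraries by its level had fixed) and within codes 4 to 8 alone (1 higher, 2 lower, Yap1 −2.07, past the threshold). Leaving out single libraries gave 0, and Yap1 from −1.77 to −1.14. The 9 called lists became 0 with an estimated correlation and 0 with directional fry, and 5 (without LYT016) to 13 (without LYT014) with 1 library left out. With arrayWeights 6 lists were called, 4 of them shared, which ended the cell cycle, basement membrane, fibrillar, PDGF and integrin, and YAP and TAZ target calls. Their medians were then −0.41, −0.06, −0.06, −0.05 and −0.15, so the last was not smaller than without weights. The contractile call was also lost with linear pseudocounts of 1 and 16, the macrophage mean as covariate, voom and codes 13 to 17 alone. The YAP and TAZ target call was lost under 13 of 29 alternatives, among them the stricter filter, a linear pseudocount of 1, voom, the length and GC trend removed and codes 4 to 8 alone. The Hippo, ribosomal and oxidative phosphorylation calls were lost within codes 4 to 8 alone, and the Hippo call stayed without Yap1 in its list (−0.20). With 7 libraries the 13 called lists became 0 with an estimated correlation and 0 with directional fry. The mixed test of fry, which ignores direction, called 2 (Hippo, adjusted p = 0.000124, and vascular smooth muscle, 0.0340) and 0 with 9 libraries, but without Yap1 in the Hippo list it called 0 with 7 libraries (adjusted p = 0.237 and 0.0680). The camera call of the Hippo list without Yap1 stayed in the fit without covariates (−0.09). With the code set as covariate the YAP and TAZ target, ribosomal and oxidative phosphorylation calls were lost. They became 6 with the stricter filter, 8 with arrayWeights, and 5 and 8 with linear pseudocounts of 1 and 16. They became 6 with the macrophage mean as covariate, which also ended the YAP and TAZ target, basement membrane, PDGF and integrin, and cell cycle calls. The medians of these lists were −0.14, −0.11, −0.11 and −0.03 with that covariate and −0.10, −0.11, −0.12 and −0.54 without it. The called lists became 7 with the length and GC trend removed, and 5 (without LYT006) to 13 with 1 library left out (8 without LYT004, 7 without LYT016). Genes became 7 higher and 18 lower with the code set as covariate, 8 and 17 with the macrophage mean as covariate, 5 lower with voom, and 1 and 1 with treat at a minimum of 0.5, which by construction asks for a larger change. Leaving out single libraries, with fewer samples, gave 1 to 3 higher and 1 to 8 lower (1 and 5 without LYT004, 1 and 1 without LYT006, 5 lower without LYT008, 4 without LYT016 and 4 without LYT017), and Yap1 from −2.28 to −2.17. Directions reversed for the interferon list (0.16) and the endothelial list (0.23) within codes 4 to 8 alone, and for the macrophage list with 7 libraries without LYT016 (−0.10), while its highest median, without LYT017, was 0.30. The contractile list with 7 libraries had a negative direction under each alternative and lost the call only with an estimated correlation and directional fry. None of those alternatives included LYT013 or LYT014, and with 9 libraries the contractile call was lost under 12 of 29. The median difference over all genes lay between −0.01 and 0.02 under each scaling. Except where stated, the cause was not tested. The count-model alternative was not run, because the deposited unit is a transformed value.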

Other observations

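The replacement of the cell cycle and matrix test described here was made after its first result was seen, as were the list members named.

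The remaining lists were not called in the 7 libraries, though several members passed adjusted over the list alone. Of 19 retinoid genes (median 0.05, camera adjusted p = 0.416), the retinoic acid receptor Rara was higher in YAP-deleted libraries by 0.40 ± 0.08 log2 units (SE, 4 control and 3 YAP-deleted libraries) and the retinaldehyde dehydrogenase Aldh1a3 by 1.05 ± 0.26. Of 26 cholesterol and fatty acid synthesis genes (median 0.08, adjusted p = 0.121), the lipogenic transcription factor Srebf1 was higher by 0.47 ± 0.08. None of these 3 passed over all genes, with limma adjusted p-values of 0.389, 0.533 and 0.239. TGF-beta genes had a median of 0.08 (camera adjusted p = 0.0982), matrix processing −0.09 (0.302), interferon response −0.06 (0.304), growth factors −0.05 (0.595), glycolysis and hypoxia 0.02 (0.304), the unfolded protein response −0.03 (0.595), and apoptosis, p53 and senescence 0.01 (0.595). The 4 erythroid genes, not tested as a list, averaged 6.29 in control and 5.86 in YAP-deleted libraries.

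A hypothesis set down beforehand was that the libraries rich in cell cycle transcripts are also the matrix-rich ones. It was first tested as a correlation of the 2 list means over all 9 libraries, and that test met the criterion set for it. The cell cycle means were then seen to fall into separate clusters, so that a pooled correlation is not a valid summary and is not reported, and the test was replaced, after that result was known, by a correlation inside a cluster of at least 6 libraries. With a gap of over 1 log2 unit between clusters, also chosen after the values were seen, the largest cluster held 5 libraries, so no correlation is reported and the relation stays open. The fibrillar matrix means were 13.87, 13.82 and 13.60 in LYT004, LYT005 and LYT008, whose cell cycle means were 9.74, 10.15 and 9.69, and 12.72 to 13.35 in the others, whose cell cycle means were 6.99 to 8.51.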
